A study of Mus musculus with 9 samples.

How the data were processed

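RNA from CD4+ T cells sorted from the colons of Rag1-deficient recipients was measured in 9 libraries, 4 from transfers of CD160 knockout cells and 5 from transfers of littermate control cells. Libraries were full-length cDNA libraries of the SMART-Seq2 kind from polyadenylated RNA, sequenced in paired-end mode, per the labels' protocols. The labels give separate titles for the libraries but do not say whether each comes from a separate recipient, so p-values measure the spread between these libraries.

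The deposited table holds TPM values, transcript abundances scaled by the authors to the same total in each of the 9 columns. The submitters' processing notes name Trimmomatic 0.32, Bowtie2 2.2.9, RSEM 1.2.31 and the genome build GRCm38, without stating their settings. TPM corrects for transcript length and total but keeps no depth, so the depth per library and the counting error behind each value are unknown and no floor or interval based on counts is given. In TPM a few very abundant transcripts lower all other values in a library. Groups and replicate numbers follow the titles.

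Symbols, written in capitals in the table, were matched to a RefSeq gene table and the GENCODE annotation of GRCm38: 22486 matched a RefSeq symbol, 444 a synonym and 425 a GENCODE name, and 60 had no match. Coordinates and the longest transcript length of each gene come from these annotations, and 98.9% of the tested genes had a length.

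The comparison used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) on log2(TPM + 1), over genes with at least 1 TPM in at least 4 libraries, 11495 in all. Benjamini-Hochberg adjustment ran over all tested genes with a threshold of 0.05. Log2 differences are knockout minus control on the log2(TPM + 1) scale, which understates the change of genes at low values. Fixed gene lists, 35 in number, covered T helper and effector programs, interferon responses, metabolism, markers of other cell types and signs of RNA quality. The 30 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Marker lists of other cells were also compared as mean log2(TPM + 1) per library with an exact two-sided permutation test over all splits of the 9 libraries, or of the 8 without control replicate 1. Groups of 4 and 5 libraries reach an exact p of 0.0159 at the smallest and groups of 4 and 4 reach 0.0286.

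The tests, lists, filters, the choice of genes to name and the first set of other processing choices were fixed before the data were examined. Genes were named as follows: Cd160; the 10 called genes with the largest positive and the 10 with the largest negative difference whose library values do not overlap, with free places filled by the smallest unadjusted p and named as not called; up to 4 genes of each biology list by smallest unadjusted p; and up to 3 most abundant genes of each cell or quality list. Gene models, pseudogenes and receptor segments were counted but not named among the largest differences. Of the 112 genes this gives, 67 are printed, a selection made after the values were seen, and 6 further genes (Ets1, Tbx21, Ifng, Il23r, Il17a and Ccl1) were added after their values were seen. Among the named genes left out is a gene whose result is not reported here.

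The other processing choices were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, median-of-ratios and quantile scaling, robust variance estimation, library quality weights, a covariate built from markers of other cells, the replicate number as a block, an exact test per gene, and leaving out each library in turn. After control replicate 1 was seen to differ, fits without it were added with a macrophage marker covariate, with median-of-ratios scaling and with the block. No library was left out of the first fit.

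The fit was tested on simulated data made from the real values with 200 genes changed by known folds. Each gene was drawn on its own from a normal distribution with its mean and its spread within groups. Correlation between genes and a single deviating library were thus not modelled, so the counts do not describe recovery in the real data. With 9 libraries and 11495 genes, 2 of 67 genes changed 2-fold, 24 of 67 changed 4-fold and 36 of 66 changed 8-fold were recovered, with 5 false calls. In the 8 other libraries, over 11457 genes, these were 48 of 67, 61 of 67 and 60 of 66, with 12 false calls. A simulated list left unshifted had an unadjusted camera p of 0.0369 with 9 libraries and 0.471 with 8, and a shifted list 3.64e-16 and 7.01e-46. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.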

Results

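Colonic CD4+ T cells were profiled by RNA sequencing after T cell transfer colitis. In this model, naive T cells given to mice without T and B cells drive inflammation of the large intestine. The donor cells, naive CD4+ CD45RBhigh T cells, came either from mice lacking CD160 or from littermate controls, and the recipients were Rag1-deficient mice. CD160 is an immunoglobulin-family receptor of lymphocytes that binds the TNF receptor family member HVEM. At the height of disease the CD4+ T cells were sorted from the colon, giving 4 libraries with CD160 knockout cells and 5 libraries with control cells. The comparison asks how the loss of CD160 alters the transcripts of T cells in the inflamed colon, within a study of IL-23 receptor signalling in colitogenic Th1-like cells. The deposited values are TPM, the abundance of each gene's transcripts corrected for length and library total, and the sequencing depth behind them is unknown.

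One control library differed from all the others. Control replicate 1 had 7308 genes at 1 TPM or more, whereas the other 8 libraries had between 11088 and 11711. Its median Spearman correlation across genes with the other libraries was 0.737, against 0.936 to 0.955 for the rest. Genes with transcripts under 1000 bp took 56.2% of its TPM, against 27.2% to 31.8% elsewhere, and mitochondrial genes took 9.43%, against 3.26% to 4.39%. The ribosomal protein transcript Rps27 alone stood at 46799 TPM in this library and averaged 12387 ± 767 TPM (SD, n = 4) in the other controls. With this library the median log2 difference of all tested genes was 0.46, and without it -0.014. Results are therefore given from all 9 libraries, and for the main comparisons also without control replicate 1.

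**Figure D1:**
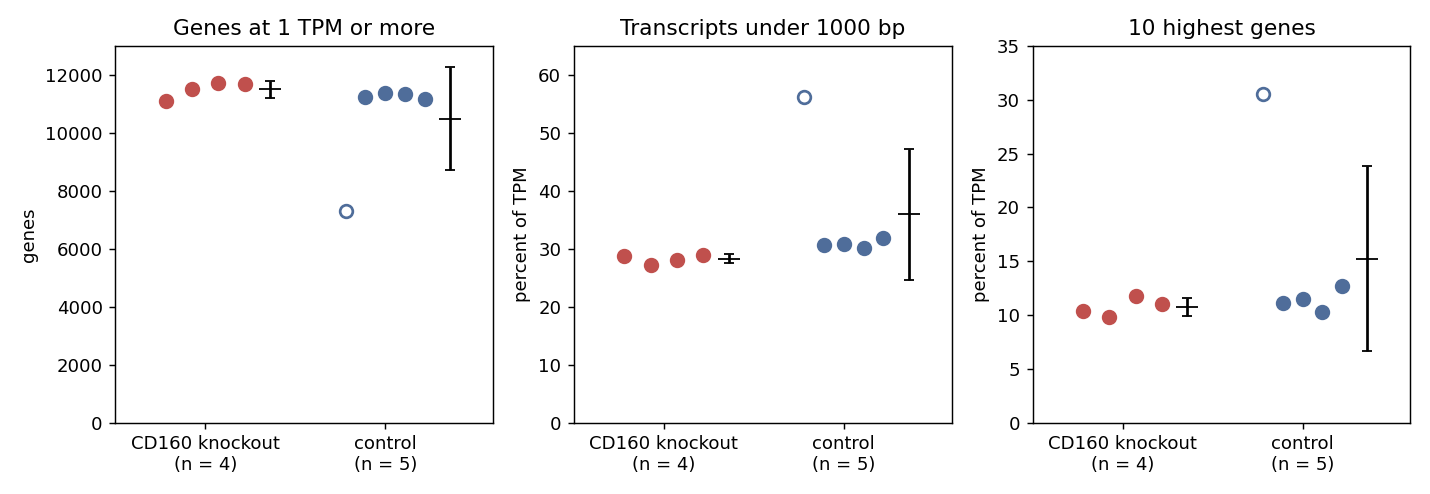
Genes at 1 TPM or more (count), and the percent of TPM in genes with transcripts under 1000 bp and in the 10 highest genes, per library; points are libraries, the open point is control replicate 1, and bars are the group mean and SD. Control replicate 1 has 7308 genes, 56.2% and 30.5%, apart from all 8 other libraries.

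Cd160 transcripts were lower in every knockout library than in any control library, but were not absent. Cd160 (chromosome 3, 96798763 to 96829351, GRCm38) stood at 14.5, 5.44, 7.51 and 18.8 TPM in knockout replicates 1 to 4. Control replicates 1 to 5 stood at 31.8, 65.9, 212.4, 41.5 and 151.2 TPM. The group means were 11.5 ± 6.17 TPM (SD, n = 4) and 100.6 ± 78.2 TPM (SD, n = 5), a log2 difference of -2.79 with a standard error of 0.64. The exact two-sided permutation test gave p = 0.0159, the smallest that the splits of 9 libraries allow; in limma across all genes the adjusted p was 0.572. In the fit without control replicate 1 the log2 difference was -3.11 with a standard error of 0.54 and an adjusted p of 0.113. The labels do not state which part of the gene was deleted. Whether the remaining signal comes from the targeted gene outside that part, or from other cells in the sort, was not determined.

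Few single genes passed the threshold adjusted over all genes. Of 11495 genes tested with limma, 2 passed an adjusted p of 0.05: Tmod4 was higher and a sequence entry for the red fluorescent reporter protein tdTomato was lower in the knockout libraries. Tmod4, a tropomodulin that caps actin filaments in muscle, lies at 95122799 to 95129209 on chromosome 3, on the same chromosome as Cd160. Its level was 6.95 ± 2.06 TPM (SD, n = 4) in knockout and 0.53 ± 0.368 TPM (SD, n = 5) in control libraries, a log2 difference of 2.37 with a standard error of 0.29 and an adjusted p of 0.0258. The reporter entry was listed at 0 in all 4 knockout libraries and at 2.52, 8.78, 7.45, 8.45 and 5.17 TPM in control replicates 1 to 5, with an adjusted p of 0.0258. A reporter sequence read only in controls would be a genetic difference between the groups beside Cd160, and the labels name none. The comparison cannot tell effects of such a difference from those of CD160 loss. With control replicate 1 left out, 3 genes passed: the same 2 and Ets1, a transcription factor of the T cell lineage singled out after its values were seen. When the macrophage marker covariate was added to that fit, the tdTomato entry alone remained called. Ets1 stood at 160.9 ± 32.5 TPM (SD, n = 4) in knockout libraries and 475.2 ± 48.4 TPM (SD, n = 4) in control replicates 2 to 5, but at 11.4 TPM in control replicate 1. Its log2 difference was -1.57 with a standard error of 0.15 and an adjusted p of 0.0167 without that library, and -0.52 with an adjusted p of 0.772 with it.

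At an unadjusted p under 0.05 the limma fit gave 735 genes, 664 higher and 71 lower, where chance gives 575. In the 8 other libraries the same threshold gave 1472 genes, 967 higher and 505 lower. The groups did not overlap for 567 genes, 4.93% of those tested, against 1.59% by chance, and for 804 genes without control replicate 1, 7.02% against 2.86%. Leaving out any 1 of the other 8 libraries left 0 genes past the adjusted threshold in limma, with 351 to 827 at an unadjusted p under 0.05. The differences of the 2 called genes themselves moved little when each of the 9 libraries was left out, from 2.23 to 2.52 for Tmod4 and from -3.06 to -2.69 for tdTomato.

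**Figure D2:**
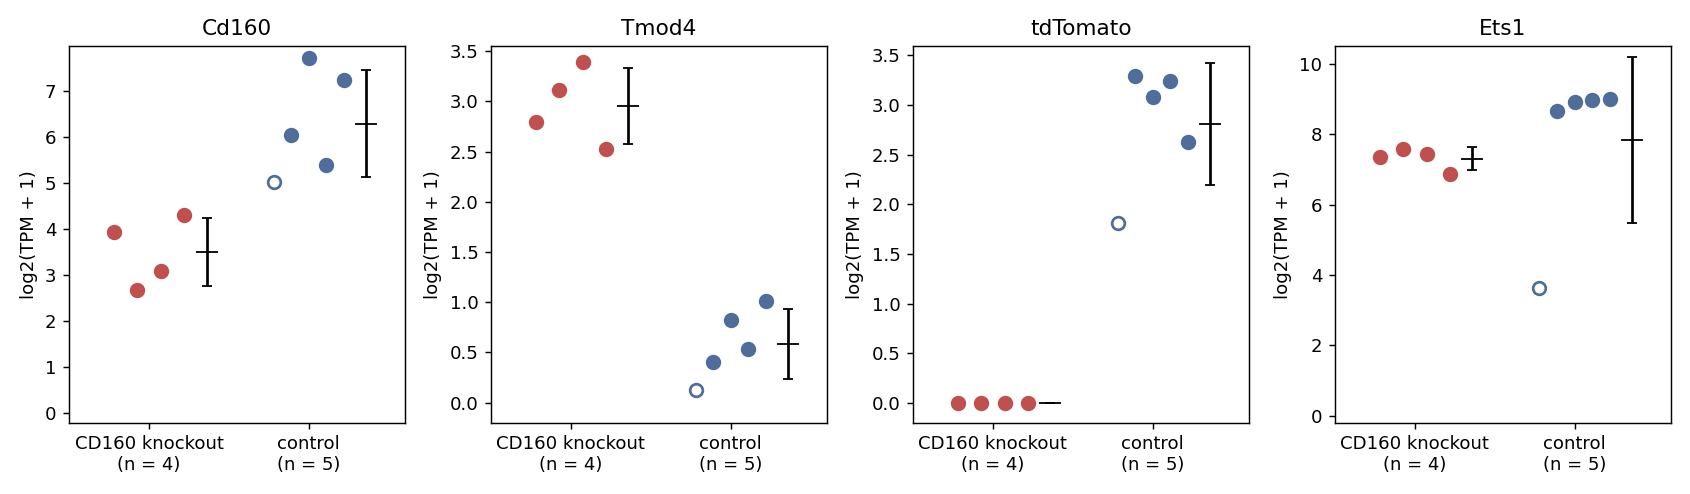
log2(TPM + 1) of Cd160, Tmod4, the tdTomato entry and Ets1 in each library; points are libraries, the open point is control replicate 1, and bars are the group mean and SD. The knockout libraries lie below every control for Cd160 and tdTomato and above every control for Tmod4, whereas for Ets1 they lie below control replicates 2 to 5 and above control replicate 1.

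The genes next in rank were not called. Among those with higher values in knockout libraries, Dclk2, a doublecortin-like kinase also on chromosome 3, stood at 10.1 ± 2.04 TPM against 1.99 ± 1.11 TPM in controls (SD, n = 4 and 5), with a log2 difference of 1.98 and an adjusted p of 0.46. Mir8099-1, a microRNA entry beside Tmod4 that shares its values with another entry, stood at 8.80, 1.16, 3.98 and 2.73 TPM in knockout replicates 1 to 4 and was listed at 0 in all 5 controls. Low-abundance genes of this kind included Lrrc16a, a regulator of actin capping, with a log2 difference of 1.19, Clec2f, a C-type lectin, at 1.55, Timp1, an inhibitor of metalloproteinases, at 1.36, Rilp, an effector of lysosome transport, at 1.2, and Ppp1r3d, a phosphatase subunit, at 0.76. Their adjusted p values in limma lay at 0.201, 0.213, 0.267, 0.483 and 0.483. Among those with lower values, most were small or mitochondrial RNAs and histone genes: the log2 differences were -1.73 for Rnu3b1, -1.55 for Rnu6, -3.18 for Snord33, -3.80 for TrnG, -1.25 for Hist1h4b and -1.24 for Hist1h4j. Amd2 and Olfr9 had -1.13 and -0.99. Mir8096 was listed at 0 in all 4 knockout libraries and at 3.49, 3.52, 9.83, 0 and 6.67 TPM in control replicates 1 to 5. All of these lower genes had an adjusted p of 0.595, and Rnu3b1 and the histone H4 genes have near-identical copies, so their values are uncertain.

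Helper T cell programs were not called as groups. In the Th1 list, 18 of 20 tested genes had positive and 2 negative differences, the list median was 0.20 above that of all genes, and camera gave an adjusted p of 0.369 (0.963 with an estimated correlation). Leaving out control replicate 1 gave a list median of -0.026 relative to all genes, with the camera direction still upward and an adjusted p of 0.849. Hlx, a homeobox factor of Th1 cells, was the only member past a threshold adjusted over the list alone, at 4.26 ± 1.5 TPM in knockout and 0.948 ± 0.496 TPM in control libraries (SD, n = 4 and 5; log2 difference 1.43, adjusted p over all genes 0.483 in limma). Ly6c2, a surface marker of activated T cells and monocytes, had a log2 difference of 1.36. In the list of Th17 and IL-23 receptor genes, 0 of 20 passed, the median was -0.053 relative to all genes, opposite in sign to the camera direction, and the adjusted p was 0.795. Its members Il6ra and Tmem176a had log2 differences of 1.58 and 1.21. They had 1.28 and 0.89 without control replicate 1, and 0.33 and -0.13 when the macrophage covariate was added to that fit. The Treg list had a median of -0.10 relative to all genes and an adjusted p of 0.737, with Izumo1r at 0.73 and Il2ra at 0.42, and 0.34 and 0.12 without that library.

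The genes central to the study's subject were looked at outside the fixed choice of genes, after their values had been seen. Tbx21, the Th1 master regulator, averaged 79.7 ± 17.4 TPM (SD, n = 4) in knockout and 71.7 ± 45.9 TPM (SD, n = 5) in control libraries, with a log2 difference of 0.74 that was -0.10 without control replicate 1. Ifng averaged 104.7 ± 25.7 and 127.1 ± 71.2 TPM, with a log2 difference of -0.10. Il23r averaged 2.65 ± 1.72 and 2.65 ± 1.53 TPM, with a log2 difference of 0.040. Il17a averaged 10.3 ± 11.4 and 7.92 ± 5.13 TPM, with a log2 difference of 0.11. Each of these differences was smaller than its standard error of 0.86, 0.49, 0.45 and 0.73. With that library left out, the log2 differences of Ifng, Il23r and Il17a were -0.44, -0.30 and -0.34, all with adjusted p values above the threshold.

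Interferon response genes were higher as groups in the knockout libraries. Of 25 tested genes in the type I interferon list, 24 had positive differences, the median was 0.30 above that of all genes, and camera with a preset correlation gave an adjusted p of 4.5e-06 (0.807 with an estimated correlation). Oas2, Oasl1 and Oasl2, which sense double-stranded RNA or relate to such sensors, passed when adjusted over the list alone, and 0 passed over all genes. Oas2 stood at 4.16 ± 1.04 TPM against 0.968 ± 0.61 TPM, Oasl1 at 4.74 ± 2.25 against 0.716 ± 0.792, Oasl2 at 16.4 ± 8.05 against 3.71 ± 2.51 and Ifit3 at 21.2 ± 5.32 against 6.63 ± 4.67 (SD, n = 4 and 5). Without control replicate 1 the median was 0.40 above that of all genes, 11 of 25 passed adjusted over the list alone, and the adjusted p was 2.94e-09 (0.429 with an estimated correlation). The interferon gamma list, with 29 of 29 positive differences, had a median 0.60 above all genes and an adjusted p of 0.00172 (0.963 with an estimated correlation). In the 8 other libraries these were 0.32 and 2.57e-06 (0.553 with an estimated correlation), and 6 of 29 passed adjusted over the list alone. Iigp1, Irf8, Gbp5 and Socs3 had log2 differences of 1.88, 1.76, 1.13 and 1.94 with all libraries and 1.44, 1.18, 0.76 and 0.91 without that library. Markers of macrophages and dendritic cells, given below, were higher in the same libraries. With these markers as a covariate, and without control replicate 1, the log2 differences of Iigp1, Irf8 and Socs3 fell to 0.70, 0.38 and 0.35 and that of Gbp5 rose to 1.03. The raw median of the interferon gamma list was then 0.31, compared with 0.30 before, while relative to all genes it was 0.20, compared with 0.32. With the covariate of other-cell markers and all 9 libraries, the type I list had a median of 0.55 relative to all genes (adjusted p 3.56e-07) and the interferon gamma list -0.23 (0.677), with Irf8 and Socs3 at -0.21 and -1.09. In that fit the median of all genes was -0.60. Control replicate 1 had the lowest means of macrophage, colon epithelium and stroma markers, at 4.20, 1.93 and 0.75. The covariate therefore also follows the overall drop of that library, and the fit does not show that other cells account for these changes.

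By the same test, naive and memory genes were also higher and cytotoxic genes lower relative to all genes. The cytotoxic list had its highest means in control replicates 3 and 5. In the naive and memory list all 17 tested genes had positive differences, with a median 0.18 above that of all genes and an adjusted p of 0.0443 (0.963 with an estimated correlation). Without control replicate 1, 12 of 17 were positive and the adjusted camera p was 0.0458 (0.553 with an estimated correlation), or 0.0617 when median-of-ratios scaling was added. Ly6c1, Ccr7 and Lef1 had log2 differences of 1.6, 1.44 and 1.07, and 1.42, 0.99 and 0.48 without control replicate 1. In the cytotoxic effector list, 14 of 22 differences were positive and 8 negative, yet the median was -0.32 relative to all genes, and the adjusted p was 0.00125 (0.891 with an estimated correlation). The raw list median of 0.14 was positive and took its lower rank from the shift of all genes, whereas without control replicate 1 the raw median was -0.34, the adjusted p 0.0309 (0.553 with an estimated correlation), and Klrd1 and Klre1 passed adjusted over the list alone. Klrd1 and Klre1, lectin-like receptors of NK and effector T cells, had log2 differences of -1.11 and -1.62, the chemokine Ccl5 -0.95 and the Fc receptor chain Fcer1g, which myeloid cells also express, 0.85. Neither list was called in the fit with the macrophage covariate and without control replicate 1, where the naive and memory median was -0.047 relative to all genes (adjusted p 0.637) and the cytotoxic median -0.022 (0.549). The mean of the 2 CD8 T cell markers showed no clear difference, at 2.8 ± 0.891 in knockouts against 3.11 ± 1.16 in controls on the log2 scale (SD, n = 4 and 5, exact p = 0.651). Cd8a had a log2 difference of -0.93 and Cd8b1 0.31, and without control replicate 3 the difference of the means was 0.012. Cd8a stood at 81.2 and 86.1 TPM in control replicates 3 and 5 and at 3.06 to 18.7 TPM in the other controls. The mean of the cytotoxic list was 7.56 and 7.55 in those libraries on the log2 scale. It was 6.97 and 6.81 in control replicates 2 and 4, within the knockout range of 6.70 to 7.11. Klrd1 and Klre1 were also highest in control replicates 3 and 5, but in control replicates 2 and 4 they too lay above every knockout library. NK markers are given below.

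The lists of oxidative phosphorylation and ribosomal protein genes were lower relative to all genes, by far less when control replicate 1 was left out. The median of 47 oxidative phosphorylation genes was -0.54 relative to all genes with an adjusted p of 1.01e-09 (0.00318 with an estimated correlation), and that of 82 ribosomal protein genes was -0.62 with 1.73e-17 (0.0282 with an estimated correlation). These medians were, without control replicate 1, -0.056 and -0.060, and the adjusted p values were 0.00186 and 0.000596 (0.553 for each with an estimated correlation). The mean difference of the oxidative phosphorylation list was 0.064 and its median -0.088 before subtraction, so that the signs differed. Ndufa1, Atp5j, Ndufb3 and Cox6c, subunits of the respiratory chain and ATP synthase, had log2 differences of -0.55, -0.46, -0.42 and -0.41, and -0.32, -0.20, -0.41 and -0.15 without that library. Rps27 and Rpl41 had -0.52 and -0.37, and -0.13 and -0.013 without that library. With the covariate of other-cell markers and all 9 libraries both lists were called in the other direction, with medians of 0.48 (adjusted p 0.0059) and 0.62 (2.57e-10) relative to all genes. As stated above, that covariate also follows control replicate 1. T cell receptor segments, 148 tested, had a median of -0.20 relative to all genes with an adjusted p of 8.26e-05 (0.963 with an estimated correlation), while their raw median was 0.25. Without control replicate 1 they were not called, with a median of -0.10 relative to all genes, a raw median of -0.11 and an adjusted p of 0.147. Single segments varied between libraries: Traj39 stood at 81.8 TPM in knockout replicate 2 and was listed at 0 in the other 3 knockout libraries, and Trbv26 had a log2 difference of 2.42.

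In all, camera called 11 of 30 tested lists, 6 higher and 5 lower, and 19 were not called, with adjusted p values from 0.0503 to 0.865. With an estimated correlation 2 lists passed, oxidative phosphorylation and ribosomal proteins. With fry 0 passed after adjustment and 3 had an unadjusted p under 0.05. Leaving out control replicate 1, camera called 15 lists, 9 of them shared with the 11, and 0 passed with an estimated correlation or fry. From the lists not called with 9 libraries, Il4ra and Il4 had log2 differences of 1.24 and -1.06, Cxcr5 and Slamf6 1.21 and 1.10, Entpd1 and Lilrb4a 1.71 and 1.23, P4ha1 and Mthfd2 1.43 and 1.43. Most of these shrank in the 8 other libraries, to 0.61 for Il4ra, 0.90 for Cxcr5, 0.44 for Slamf6, 0.99 for Entpd1, 0.63 for Lilrb4a, 0.80 for P4ha1 and 0.72 for Mthfd2, while Il4 had -1.55. With the macrophage covariate added there, Entpd1, Il4ra, Slamf6 and P4ha1 fell to 0.10, 0.22, 0.22 and 0.71, and Il4 had -1.17. Cxcr5, Lilrb4a and Mthfd2 rose to 1.42, 0.68 and 0.93. In the list of HVEM and its partners, which include CD160's ligand, 1 of 7 passed adjusted over the list alone: Ltbr, the lymphotoxin beta receptor, at 7.59 ± 2.36 TPM against 2.26 ± 1.34 TPM (SD, n = 4 and 5), while Ltb had a log2 difference of 0.54, and 0.11 in the 8 other libraries. The log2 difference of Ltbr was 1.46, 1.24 without control replicate 1 and 0.50 when the macrophage covariate was added, where 0 of 7 passed.

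**Figure D3:**
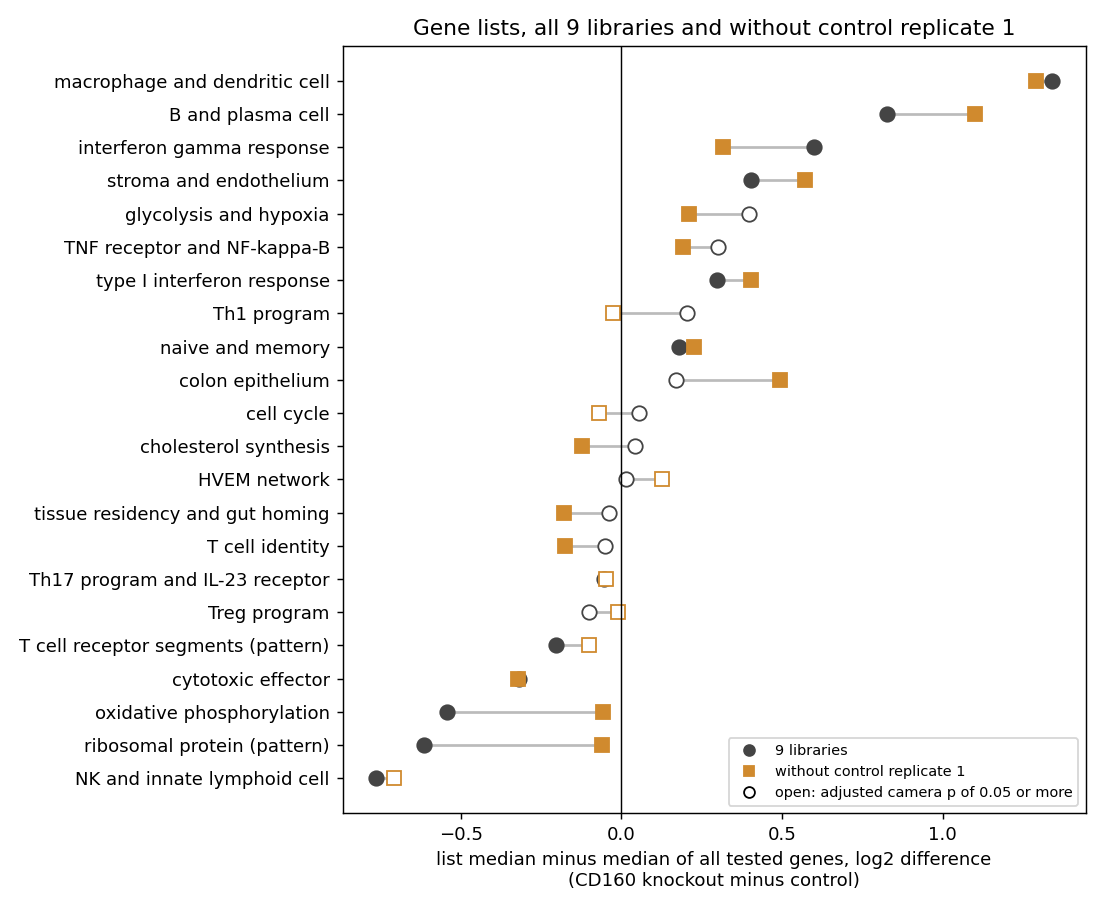
Median log2 difference (CD160 knockout minus control) of each of 22 gene lists minus the median of all tested genes, with all 9 libraries (circles) and without control replicate 1 (squares); filled symbols have an adjusted camera p under 0.05 with the preset correlation. Oxidative phosphorylation moves from -0.54 to -0.056 and ribosomal proteins from -0.62 to -0.060 without that library, while the macrophage and dendritic cell list stays at 1.34 and 1.29.

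Markers of other cell types were looked at because a sort on CD4 can hold other cells. Macrophage and dendritic cell markers had a list median 1.34 above that of all genes, the largest among the tested lists: 29 of 30 tested genes were positive, 24 passed adjusted over the list alone, 0 passed over all genes, and camera gave an adjusted p of 2.76e-18 (0.556 with an estimated correlation). Apoe stood at 10301 ± 6334 TPM in knockout and 4021 ± 3390 TPM in control libraries, H2-Ab1 at 9706 ± 2720 and 3878 ± 3169, and Cd74 at 7385 ± 1980 and 2567 ± 1893 (SD, n = 4 and 5), with log2 differences of 1.58, 1.78 and 2.08 that were 0.97, 1.23 and 1.33 without control replicate 1. The mean of the markers per library was 7.68 ± 0.437 in knockouts and 6.02 ± 1.21 in controls on the log2 scale, with 3 of 4 knockout libraries above every control, and the exact permutation p was 0.0317 (adjusted 0.159). Knockout replicate 2 (7.377) was level with control replicate 2 (7.376), and knockout replicate 1 (7.237) lay below it. Control replicates 3, 4 and 5 had 5.91, 6.85 and 5.77. Without control replicate 1 the difference was 1.2 instead of 1.66, with an exact p of 0.0571 (adjusted 0.286) and 22 of 30 genes past the threshold adjusted over the list alone. B and plasma cell markers were higher in 4 of 4 knockout libraries than in every control, at 1.92 ± 0.182 against 1.33 ± 0.294 (exact p = 0.0159, the smallest possible, adjusted 0.159), and Blnk and Igkc had log2 differences of 1.46 and 0.99. The recipients, being Rag1-deficient, lack mature T and B cells of their own. Only 1 of the 13 genes was at 10 TPM or more in all libraries but control replicate 1. These low means alone are therefore no evidence of B or plasma cells. Igkc averaged 43.0 ± 13.2 TPM in knockout and 25.4 ± 20.6 TPM in control libraries (SD, n = 4 and 5), and its source was not determined. By camera the adjusted p values were 0.0013 for B and plasma cells (0.165 with an estimated correlation), 0.0173 for stroma and endothelium (0.963), where Dcn and Col3a1 had 1.64 and 1.86 (0.90 and 1.07 without control replicate 1), and 0.0173 for lower NK and innate lymphoid markers (0.807). In the 8 other libraries the NK and innate lymphoid markers were not called (0.0868), whereas colon epithelium, with 19 of 25 positive differences, was called higher (0.0256, 0.553 with an estimated correlation). With the macrophage covariate in those libraries the stroma list was called lower (median -0.58 relative to all genes, adjusted p 0.000937, 0.746 with an estimated correlation), and neither B and plasma cells (-0.054, 0.849) nor colon epithelium (0.45, 0.637) were called.

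T cell identity genes had a median of -0.050 relative to all genes and an adjusted camera p of 0.205, which became -0.17 and 0.00103 (0.553 with an estimated correlation) without control replicate 1; adding the macrophage covariate gave -0.11 and 0.304. Cd3g had log2 differences of -0.10 and -0.37 in those fits, and Trbc2 0.17 and -0.19. None of the 10 cell type lists passed the adjusted exact test, while 2 had an unadjusted exact p under 0.05; even the list at the smallest possible exact p was adjusted to 0.159, so that test had little room to call a list.

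**Figure D4:**
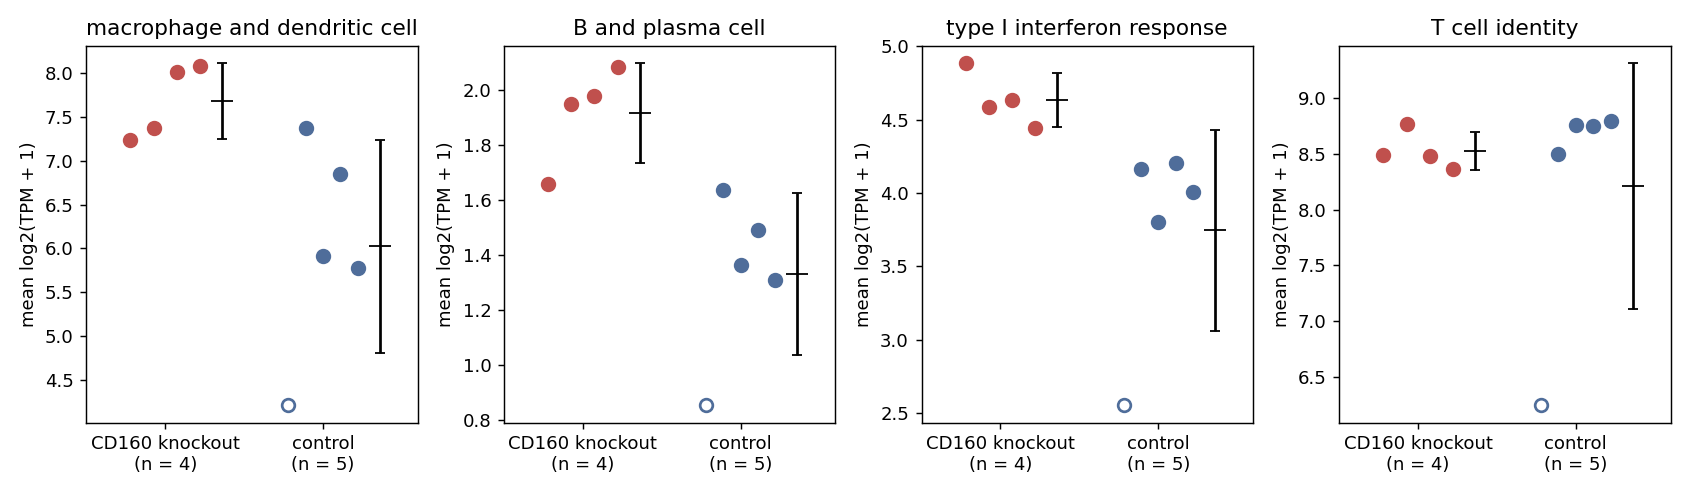
Mean log2(TPM + 1) of 4 gene lists in each library; points are libraries, the open point is control replicate 1, and bars are the group mean and SD. Macrophage and dendritic cell markers lie above every control in 3 of 4 knockout libraries, with knockout replicate 2 (7.377) level with control replicate 2 (7.376), and B and plasma cell markers in 4 of 4.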

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

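Of the tests in this part, those of transcript length and of starting material in control replicate 1 were chosen after its difference from the other libraries had been seen, and the test of other cell types was not. A value lying far from the others of its group, by Dixon's criterion, was found in 45 of 205 groups of values examined, where chance gives about 1 in 20; 41 of the 45 were values of control replicate 1.

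Control replicate 1 stood apart from the other control libraries in the number of genes at 1 TPM or more (7308 against 11182 to 11370), in its median correlation with the other libraries (0.737 against 0.936 to 0.955) and in the share of TPM in the 10 highest genes (30.5% against 10.3% to 12.7%). It also stood apart in the share of short transcripts (56.2% against 30.2% to 31.8%) and of mitochondrial genes (9.43% against 3.44% to 4.39%). Its list means on the log2 scale were far below those of the other controls for the Th1 program (3.41 against 6.10 to 6.50), the Treg program (2.15 against 3.60 to 3.74), naive and memory genes (1.71 against 3.33 to 3.67), type I interferon genes (2.55 against 3.8 to 4.21) and interferon gamma genes (4.01 against 7.15 to 7.45). The same held for oxidative phosphorylation (7.68 against 8.40 to 8.43), T cell receptor segments (1.16 against 2.21 to 2.55) and T cell identity (6.24 against 8.5 to 8.80), and for HVEM and its partners (2.79 against 4.68 to 5.07), tissue residency and gut homing (3.17 against 6.08 to 6.57), cell cycle (2.90 against 5.03 to 5.77) and glycolysis and hypoxia (3.32 against 6.1 to 6.13). Cholesterol synthesis (1.64 against 4.44 to 4.86) and TNF receptor and NF-kappa-B genes (3.10 against 5.66 to 5.94) were lower there too.

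Among single genes, control replicate 1 had far higher TPM than the other controls for Ndufa1 (1260.0), Atp5j (2014), Cox6c (2469), Rps27 (46799) and Rpl41 (31846). It had far lower TPM for the T cell genes Cd3g (580.4), Trbc2 (520.0), Ltb (136.1), Il4ra (3.74), Izumo1r (5.64), Il2ra (2.16), Slamf6 (1.07), Lilrb4a (21.1), Lef1 (1.12), Tbx21 (3.53) and Ets1 (11.4). Gbp5 (0.24), Socs3 (1.55), P4ha1 (0.92), Mthfd2 (2.15) and Dcn (2.64) were lower there as well, and Lrrc16a was listed at 0.

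Several technical explanations for the profile of control replicate 1 were weighed. Loss of long transcripts would give a falling log2 ratio with transcript length, but the Spearman correlation across 11366 genes was -0.154, smaller in size than the -0.383 of control replicate 2; genes with transcripts under 500 bp had a median log2 ratio of -0.58, and those of 500 to 1000 bp -0.23, against -1.92, -2.37 and -2.16 in the classes above 1000 bp, so a step near that length stays open. Few starting molecules would leave abundant genes at 0, and of the 5462 genes at 10 TPM or more in all 8 other libraries 0.0915% were listed at 0 here, whereas in the same count for each other library, over 1866 to 1876 genes, at most 0.107% were. Yet 10% of those genes were under 1 TPM here, against at most 0.107% elsewhere, so few starting molecules are not excluded. Cells of another type would raise their markers, and 0 of the other-cell marker lists had their highest mean in this library, but most genes were lower here (median log2 ratio -2.08), which leaves that count little room. The neutrophil and red blood cell means of 2.06 and 2.66 lay among those of the other controls (1.15 to 2.07 and 1.08 to 4.15) and did not fall with the rest. Single markers went both ways. Igkc stood at 60.6 TPM here, against 7.64 to 24.0 TPM in the other controls, and Blnk at 0.88 TPM, against 2.06 to 12.1 TPM. Other cell types are thus not excluded either. Open as well is a difference in library preparation or RNA quality, or in the recipient's disease, for which the labels give no value.

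Other values far from their group were found in single libraries. Knockout replicate 1 had a neutrophil marker mean of 3.56, against 1.75 to 1.79 in the other knockout libraries, and a mast cell and eosinophil marker mean of 1.46, against 0.20 to 0.24. Traj39 stood at 81.8 TPM in knockout replicate 2 and was listed at 0 in the other knockout libraries. Snord33 stood at 29.7 TPM in control replicate 2, against 39.4 to 42.2 TPM in the other controls.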

How the results depend on the processing

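The fits without control replicate 1 that carry a covariate, another scaling or a block were chosen after the data were seen. Cd160 was lower in the knockout libraries under all 21 alternatives, with log2 differences from -3.11 to -2.43 when each library was left out in turn. The count of 2 called genes became 3 with a pseudocount of 0.1, with 1 of the 2 kept, 3 with median-of-ratios scaling, 1 with a pseudocount of 5, 0 without a filter on low values (1174 at an unadjusted p under 0.05), 0 with a filter of 5 TPM (397), 1 with quantile normalization, 521 with library quality weights (440 higher and 81 lower) and 1 with the covariate of other-cell markers. It was 0 with an exact permutation test per gene, where 1292 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.322. Leaving out single libraries gave from 0 to 3. With control replicate 1 left out it was 1, the tdTomato entry, with the macrophage covariate and 4 with median-of-ratios scaling, Dclk2 being the fourth. Same-numbered libraries did not deviate together (correlations of -0.017, -0.093, -0.14 and -0.089), and pairs of unlike number ranged from -0.19 to 0.195. The control deviations were taken from a mean that included control replicate 1, so these values cannot tell whether the numbers pair the libraries. The replicate block over numbers 1 to 4 gave 0 called genes (727 at an unadjusted p under 0.05), and over numbers 2 to 4, without control replicate 1, 0. Of the 11 called gene lists, 2 remained with an estimated correlation and 0 with fry. All other alternatives gave 8 to 16 lists, but not always the same ones. Of the 11, direction aside, 5 were kept with the covariate of other-cell markers and 6 with quantile normalization. With library quality weights 9 were kept, and with robust variance estimation 11. The count of other-cell lists was 0 in every fit, but it could hardly change, since even a list at the smallest exact p was adjusted to 0.159 with 9 libraries and 0.286 with 8. The share of higher genes among those at an unadjusted p under 0.05 was 90.3%, 75.1% with median-of-ratios scaling, 60.2% with quantile normalization, 65.7% without control replicate 1 and 20.4% with the covariate of other-cell markers; the median of all genes moved from 0.46 to 0.018, -0.0011, -0.014 and -0.60. Changes of sign occurred in results that were not called or in lists lost with an estimated correlation, except for the 2 lists of oxidative phosphorylation and ribosomal proteins. With the covariate of other-cell markers the list medians relative to all genes were -0.46 for Th1, 0.042 for Treg, -0.23 for interferon gamma, -0.16 for glycolysis and hypoxia, -0.52 for cholesterol synthesis, -0.052 for TNF receptor and NF-kappa-B, -0.089 for cell cycle, 0.48 for oxidative phosphorylation and 0.62 for ribosomal proteins, these last called higher with adjusted p values of 0.0059 and 2.57e-10 and cholesterol synthesis called lower with 0.00137. In the same fit the log2 differences were -0.16 for Tmem176a, -0.63 for Il4ra, -0.23 for Izumo1r, -0.31 for Il2ra, -0.76 for Slamf6, 0.29 for Ccl5, -0.34 for Ltb, -0.64 for Entpd1, -0.33 for Lilrb4a, -0.48 for Lef1, -0.21 for Irf8 and -1.09 for Socs3. They were 0.032 for Ndufa1, 0.20 for Atp5j, 0.26 for Cox6c, 0.45 for Rps27, 0.56 for Rpl41, -0.94 for Apoe, -0.40 for H2-Ab1, -0.50 for Cd74, -0.68 for Trbc2, -0.25 for Blnk, -0.71 for Col3a1 and -0.97 for Dcn. For P4ha1 they were -0.26, for Mthfd2 -0.34, for Tbx21 -1.25, for Il23r -0.85 and for Il17a -0.90. Library quality weights gave -0.17 for the cell cycle list (adjusted p 0.00358), -0.12 for cholesterol synthesis, -0.070 for Th1, 0.070 for Th17, 0.052 for Treg, -0.028 for Ltb, -0.20 for Trbc2, -0.22 for Tbx21, -0.20 for Il23r and -0.20 for Il17a. Median-of-ratios scaling gave -0.092 for the HVEM list, -0.013 for cell cycle, -0.056 for cholesterol synthesis, -0.29 for the mean of T cell identity markers, -0.093 for Il2ra, -0.074 for Ltb, -0.45 for Trbc2, -0.23 for Il23r and -0.33 for Il17a, and without control replicate 1 -0.026 for the Th1 list, -0.071 for cell cycle, -0.12 for cholesterol synthesis, -0.18 for Trbc2, -0.099 for Tbx21, -0.30 for Il23r and -0.34 for Il17a. Quantile normalization gave 0.10 for the T cell identity list, -0.019 for cell cycle, -0.012 for cholesterol synthesis, -0.14 for Il2ra, -0.36 for Il23r and -0.40 for Il17a. Without a filter the list medians were 0.20 for Th17, 0.17 for Treg, 0.21 for tissue residency and 0.20 for T cell identity; a filter of 5 TPM gave -0.048 for HVEM and -0.013 for cholesterol synthesis, and a pseudocount of 0.1 -0.070 for HVEM, -0.0057 for cell cycle and -0.046 for cholesterol synthesis. A pseudocount of 5 gave 0.012 for Treg, 0.023 for tissue residency, 0.14 for T cell identity and -0.00065 for Il23r. With the macrophage covariate and without control replicate 1, the covariate being built from the macrophage list itself, the values were -0.047 for naive and memory, -0.19 for cholesterol synthesis, -0.054 for B and plasma cells, -0.026 for macrophages and dendritic cells and -0.58 for stroma. There Tmem176a had -0.13, Fcer1g -0.094, Ccl5 0.26, Apoe -0.94, H2-Ab1 -0.15, Trbc2 -0.014, Blnk -0.58, Dcn -0.45, Ifng 0.34, Il23r -0.37 and Il17a -0.11. The replicate block gave 0.16 for Ifng. Leaving out single libraries gave ranges of -0.026 to 0.36 for the Th1 list, -0.26 to 0.12 for Th17, -0.12 to 0.21 for HVEM, -0.18 to 0.060 for tissue residency, -0.071 to 0.19 for cell cycle, -0.12 to 0.12 for cholesterol synthesis, -0.042 to 0.50 for colon epithelium, -0.17 to 0.46 for the mean of T cell identity markers, -0.72 to 0.012 for CD8 T cell markers, -0.41 to 0.0085 for NK markers and -0.44 to 0.15 for mast cell markers. The ranges were -0.19 to 0.30 for Trbc2, -0.10 to 1.06 for Tbx21, -0.44 to 0.16 for Ifng, -0.30 to 0.23 for Il23r and -0.49 to 0.55 for Il17a. Apart from fewer libraries or genes tested, the cause of these changes was not tested. For the genes and the 22 lists in the text, the sign stayed the same in all other comparisons with their alternatives; the threshold was newly passed in 43 pairs of a gene and an alternative and 35 of a list and an alternative, and lost in 26 and 37. Depth is unknown, so its limit on low genes could not be given.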

Other observations

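Tests of the macrophage marker difference without control replicate 1, the fits without that library that carry a covariate, and the splits without it or with library quality weights, were chosen after the data were seen; leaving out each library in turn was fixed beforehand. Beside Ets1, the chemokine Ccl1, a ligand of CCR8 made by activated T cells, was singled out after its values were seen. Ccl1 stood at 425.9, 226.6, 128.9 and 268.1 TPM in knockout replicates 1 to 4 and at 62.6, 78.8, 38.8 and 68.5 TPM in control replicates 2 to 5, but at 419.6 TPM in control replicate 1. Its log2 difference was 1.42 with a standard error of 0.65 and an adjusted p of 0.745 in limma, and 1.98 with 0.35 and 0.113 without that library; over 21 alternatives the adjusted p ranged from 0.0189 to 0.889. Table entries named EGFP_IRES_IL23R and ICRE were listed at 0 in all 9 libraries, whereas the tdTomato entry was above 0 in all 5 controls, and the labels name no reporter allele.

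With control replicate 1 left out, some gene groups that were not called with 9 libraries were called by camera with the preset correlation. Tissue residency and gut homing genes were lower, 14 of 17 with negative differences (adjusted p 0.0282, 0.553 with an estimated correlation), as were cholesterol synthesis genes, 17 of 22 (0.0466, 0.633 with an estimated correlation). Adding the macrophage covariate ended both calls, with adjusted p values of 0.39 and 0.119 and 8 of 17 and 14 of 22 negative. The median relative to all genes went from -0.18 to -0.063 for tissue residency, but from -0.12 to -0.19 for cholesterol synthesis, which did not shrink. Glycolysis and hypoxia genes, 19 of 22 with positive differences (0.00241), and TNF receptor and NF-kappa-B genes, 16 of 20 (0.00676), were higher, each with an adjusted p of 0.553 with an estimated correlation, and stayed called with that covariate (0.0116 and 0.0252, each 0.746 with an estimated correlation). Among Th2 genes Il4ra was higher, with a log2 difference of 0.61, and Il4 lower, with -1.55, both past the threshold adjusted over the list alone. With the covariate 0 Th2 genes passed, and Il4ra had 0.22 while Il4 still had -1.17. Cell cycle genes had 26 of 35 negative differences and an adjusted p of 0.169, but 33 of 35 positive with 9 libraries (0.675) and 35 of 35 positive with the macrophage covariate (3.51e-06, 0.746 with an estimated correlation), so their direction depended on the fit.

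Chance could not be excluded for the counts of called genes and lists. With 9 libraries, 8 of 100 splits of the libraries into 4 and 5 gave at least the real count of 2 called genes, and the highest other split gave 9. For the 11 called lists, 34 of 100 splits gave as many and the highest other gave 19. In the 8 other libraries, 4 of 35 splits gave at least 3 genes, with 9 the highest other, and 5 of 35 gave at least 15 lists, with 20 the highest other. With library quality weights, 9 of 100 splits gave at least 521 genes and the highest other gave 1333; control replicate 1 received a weight of 0.0123 in that fit, against 0.70 to 2.97 for the others.

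Macrophage and dendritic cell markers were higher in the knockout libraries. Control replicate 1 alone does not account for this, since without it the difference of the list means was 1.2 on the log2 scale, with 4 of 4 knockout libraries above the control median. RNA of macrophages or dendritic cells in the sorted population is a candidate source. Within groups the 30 markers deviated together, with a median pairwise correlation of 0.80, against 0.13 for random lists of the same size (95th percentile of 1000 such lists 0.29). Random lists are a weak comparison, since genes regulated together also deviate together. The correlation estimated by camera in the 8 libraries was 0.707 for the markers, 0.818 for cell cycle and 0.685 for stroma, and at most 0.501 in the other tested lists. It does not single out RNA of other cells as the source. In controls Apoe, H2-Ab1 and Cd74 averaged 4021, 3878 and 2567 TPM, above the T cell genes Cd3g (1279) and Trbc2 (1511). The same order held in knockout libraries, so RNA of these markers was abundant despite the sort on CD4. Of the 32 markers, 0 are held by another list and 23 were at 10 TPM or more in all 8 libraries other than control replicate 1, Apoe, H2-Ab1 and Cd74 being the most abundant. The lack of shared genes was fixed when the lists were written. It does not show that the markers are independent of the interferon response, and a covariate built from them may take up part of that response. With these markers as a covariate, without control replicate 1, the type I interferon list had a median 0.33 above all genes and an adjusted p of 0.00376 (0.746 with an estimated correlation), compared with 0.40 before, and the interferon gamma list 0.20 and 0.0149 (0.757), compared with 0.32; the genes passing adjusted over the list alone went from 11 and 6 to 0 and 0. The differences did not vanish: the difference of the type I list means per library was 0.59 (95% interval 0.27 to 0.92) before and 0.51 (-0.032 to 1.04) with the covariate, and that of the interferon gamma list 0.34 (0.13 to 0.55) and 0.34 (-0.020 to 0.70). As the intervals with the covariate include 0, whether the interferon genes share a source with the markers stays open, and more myeloid cells in colons that received knockout cells stays open as a biological explanation that was not tested.

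Tmod4 and its neighbour Mir8099-1 lie near Cd160 on chromosome 3, Tmod4 at a distance of 1.68 Mb, which raises the question of variants carried along with the targeted locus. Within 10 Mb of Cd160, 30 of 211 genes (14.2%) had an unadjusted p under 0.05 in limma without control replicate 1, a percentile of 67.3 among 443 windows of the same size (median 12.3%), so that a difference of strain or donor origin at the locus cannot be told apart from the background by this count, which a few altered genes would hardly move. Dclk2, at about 10 Mb, fell outside this window. Macrophage RNA as the source of the Tmod4 difference is argued against by the fit with the macrophage covariate, where its log2 difference was 2.58 with a standard error of 0.32 and a 95% interval of 1.85 to 3.31, compared with 2.26 and 0.23 without it. The adjusted p of Tmod4 in that fit was 0.145, since its standard error grew 1.39-fold and its difference 1.14-fold, and the covariate took a residual degree of freedom. At the same rank among the genes, the smaller ratio of difference to error alone gives an adjusted p of 0.0806 and the lost degree of freedom alone 0.0343. An effect of CD160 itself on these genes was not tested.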
